A study of Drosophila melanogaster with 6 samples.

How the data were processed

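The data were polyA RNA sequencing counts from Drosophila melanogaster embryos of 20 to 22 hours after egg laying, close to the end of embryogenesis. Per the labels, eggs were collected for 2 hours at 25 °C and developed for 20 hours, 100 embryos were pooled per sample, RNA was isolated with Trizol and treated with DNase I, and libraries were made from 1 µg of RNA with the NEBNext Ultra Directional kit, which marks strand. There were 6 samples in 2 groups of 3. The mutant group carried lola-O, a mutation described in the labels as a knockout of isoform O of lola, over the deficiency Df(2R)ED2076; the control group carried a wild-type second chromosome over the same deficiency. Samples were grouped by their titles. The descriptions call each of the 3 controls replicate 1, and the extract protocol names mutant embryos for all 6 samples, so the titles and genotypes decided the group. The labels do not say whether the 3 samples of a group came from separate crosses or collections, so the p-values measure the spread between these samples, which may be technical.

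The deposited values are whole-number read counts per FlyBase gene identifier, with no normalization, per the deposited files. Per the submitters' processing notes, STAR 2.5.2b, Subread 1.5.1, SAMtools 1.3.1 and bedtools 2.25.0 were used with genome build BDGP6. The roles of these tools, the strand setting of the counting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Counts of members of gene families with similar copies, and of genes that overlap on either strand, are therefore uncertain.

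Each file held 17559 gene identifiers. Of these, 17253 matched the Ensembl release 115 annotation of BDGP6.54 and its name table, which gave symbols, positions and the length of the longest annotated transcript; 306 did not match and kept their identifiers, and they held 4.37% to 4.49% of the counts. BDGP6.54 is a later release name than the one in the processing notes, and positions are given in BDGP6.54. The current identifier of lola in that annotation, FBgn0283521, was not among those analysed here. FBgn0005630 was; earlier FlyBase releases used it for lola, which is background knowledge and not a pairing made by the name tables used here.

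Total counts ranged from 16217213 to 22759638 per sample. A count of 0 in a library allows up to 3 counts, which is 0.132 to 0.185 CPM, the count scaled to a common library size of 1e6. Intervals from counts cover counting error only, since reads were not marked by molecule. Replicates of each group differed by more than sampling noise, with a chi-square per degree of freedom of 1.94 to 6.14 over genes with at least 100 counts in a pair, so no library was treated as a copy of another.

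Changes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter by group, robust quasi-likelihood fits (glmQLFit and glmQLFTest) of mutant against control without a replicate term, and Benjamini-Hochberg adjustment over the tested genes, with calls at adjusted p below 0.05. All tests were 2-sided. The filter kept 10312 genes. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM are TMM-scaled and given as mean ± SD over 3 samples. Fold changes are mutant over control throughout.

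The 30 gene lists, the rule for naming genes, the tests and most of the other settings were fixed before the data were examined. Lists with at least 5 tested members (28 of 30) were tested on log2 CPM (prior count 2) with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over lists. The replication-dependent histone list had no tested member, and the chorion and vitelline membrane list had 2, Cp190 and Cp110, which are centrosomal proteins caught by the name pattern; neither list was tested. The text names FBgn0005630, Tbh, futsch and the tested octopamine and tyramine genes; the 12 higher and 12 lower genes with the largest fold change among those that passed, with a mean of at least 1 CPM and groups that do not overlap; and up to 4 members with the smallest adjusted p in each list that passed and in the neuron, axon guidance, glia, muscle and cuticle lists. Genes named outside this rule were chosen after their values were seen, and the text says so. Fisher's exact tests compared the share of changed genes between each of 6 chromosome arms and the others, adjusted over arms, and between genes starting within 1 Mb of the midpoint of lola and the others.

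The other settings tried were RLE and upper-quartile scaling, no low-count filter and a filter of 5 CPM in 3 samples, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each sample, leaving out the 20 most abundant genes, an estimated inter-gene correlation, fry, a prior count of 0.5, a requirement of 2-fold change, and windows of 0.5 and 2 Mb. A correction for transcript length was added after the data were seen: for each sample a lowess trend (span 0.3) of log2 CPM deviations on log2 transcript length entered edgeR as an offset, or was subtracted before camera. In addition, each list median was placed among the medians of 10000 random lists matched on transcript length (20 bins) and level (5 bins).

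The procedures were tested on simulated counts drawn from the means and library sizes of the real samples, with 200 changed genes. For the comparison of the 2 genotypes, over 10238 tested genes, edgeR recovered 64% of genes changed 1.2-fold, 84% at 1.5-fold, 100% at 2-fold and 98% at 4-fold, and 4.15% of its calls were on unchanged genes. The simulated counts also held a raised glycolysis list, but no trend with transcript length and far fewer changed genes than were called in the real data. The share of calls on unchanged genes may therefore differ in the real comparison. Figures were drawn with matplotlib 3.10.9.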

Results

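RNA sequencing counts were analysed from pools of 100 Drosophila embryos at 20 to 22 hours after egg laying, 3 from lola-O mutants and 3 from controls. The locus lola encodes a family of BTB zinc-finger transcription factors, made by alternative splicing, that act in axon growth and guidance. In BDGP6.54 it lies on 2R from 10481894 to 10543291 on the minus strand, with 24 annotated transcripts. The comparison asked which transcripts differ in late embryos that carry a mutation of isoform O over a deficiency, against embryos with a wild-type chromosome over the same deficiency. Total counts were 19532578, 16217213 and 20518120 for mutants 1, 2 and 3, and 21507704, 22759638 and 17480430 for controls 1, 2 and 3, with 12466 to 12773 genes counted at least once. Mitochondrially encoded genes took 15.95% to 18.10% of counts, of which mt:lrRNA alone took 10.6% to 12.6%. The first principal component of log2 CPM held 62.6% of the variance and separated the groups, with scores of -17.7 to -17.1 in the mutants and 16.2 to 18.6 in the controls.

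The locus itself was examined first. FBgn0005630, the identifier that earlier FlyBase releases used for lola and that the name tables used here do not pair with it, had 350 ± 13.2 CPM in the mutants and 413 ± 11.04 CPM in the controls (SD, n = 3 each). The raw counts were 6807, 5817 and 6851 in mutants 1 to 3 and 8695, 9341 and 7562 in controls 1 to 3. The gene fell by 0.24 on the log2 scale (SE 0.029, edgeR adjusted p = 2.73e-10). This count sums over all isoforms of the gene, so it does not measure isoform O and does not check the genotype. The transcript-length correction was not applied to FBgn0005630, because this identifier did not match the annotation. The length of the annotated lola locus was not used in its place. The decile of genes with the longest transcripts had a median log2 fold change of -0.14. Whether the fall of FBgn0005630 follows length was therefore not tested.

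Of 10312 tested genes, 4093 (39.7%) differed between the mutant and control libraries by edgeR, 2087 higher and 2006 lower in the mutant. With the transcript-length correction, 2817 of these genes still passed. Most differences were small: the median change of these genes was 1.17-fold, and 95.9% changed by less than 2-fold. At least 2-fold changes were found for 167 genes, 92 higher and 75 lower. The common biological coefficient of variation was 2.78%. The labels do not say whether the samples of a group were separate collections, so this spread may be technical.

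Among genes with a mean of at least 1 CPM and groups that do not overlap, the largest increases included secreted immune and stress peptides. TotA (3R, 20871036 to 20871700), a stress-induced Turandot peptide, had 5.55 ± 0.249 CPM in the mutants and 0.280 ± 0.129 CPM in the controls (SD, n = 3 each), a log2 fold change of 4.31 (SE 0.26, edgeR adjusted p = 8.65e-23). The Bomanin genes, which encode short secreted peptides of the Toll immune response, rose in 4 of the 12 leading positions: BomBc1 by 4.84, BomT3 by 4.47, BomS2 by 3.63 and BomBc3 by 3.01 on the log2 scale. BomBc1 had 5 counts in the 3 controls together, 4 of them in control 2, and ranged from 4.26 to 6.29 with a sample left out. For TotC, for Tep1, which encodes a thioester-containing protein of the complement-like family, and for CG16772, the 3 controls together held only 2, 2 and 3 counts. The ratios of their summed counts, mutants over controls, were 63.9 (95% interval 17.3 to 534), 63.4 (17.1 to 530) and 41.1 (13.7 to 203), with intervals for counting error only. Both control counts of TotC came from control 2 and both of Tep1 from control 1; with a sample left out, the log2 fold changes ranged from 5.21 to 8.30 for TotC, 5.16 to 8.30 for Tep1 and 4.596 to 5.997 for CG16772. Crys, a crystallin gene, rose by 4.68, although 13 of its 15 control counts came from control 2; it ranged from 4.17 to 6.79 with a sample left out. CG43175 rose by 3.17, the Tweedle cuticle gene TwdlM by 3.06 and CG1077 by 2.98. All 12 passed edgeR with adjusted p of 7.27e-11 or less. The Bom, Tot and Twdl genes belong to families of similar copies, so the division of reads among them is uncertain.

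Under the same limits, the largest decreases were in genes of mixed function. The non-coding gene lncRNA:CR44701 (2L, 9887039 to 9887389) had 0.130 ± 0.0720 CPM in the mutants and 5.15 ± 0.446 CPM in the controls (SD, n = 3 each), a log2 fold change of -5.29 (SE 0.32, edgeR adjusted p = 5.11e-23). CG14852 had a log2 fold change of -4.76, CG13135 of -4.39 and CG8245 of -3.88. BomS6, a further Bomanin gene, moved against its relatives at -3.37, with 0.525 ± 0.147 CPM in the mutants and 5.47 ± 0.582 CPM in the controls (SD, n = 3 each). The chitinase gene Cht4 had -3.02, the eye pigment transporter gene w -2.96, CG33511 -2.90 and EndoGI, an inhibitor of endonuclease G, -2.81. The gene w lies on the X, and sequence differences between the groups at w or elsewhere off the second chromosome were not examined. CR30029 had -2.17, CG10081 -2.10 and lncRNA:CR44603 -1.81. All 12 passed edgeR with adjusted p of 6.93e-07 or less. CG14852 overlaps CG31313, and EndoGI overlaps twe, on the opposite strand; unless the counting used strand, reads of these pairs cannot be told apart.

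**Figure D1:**
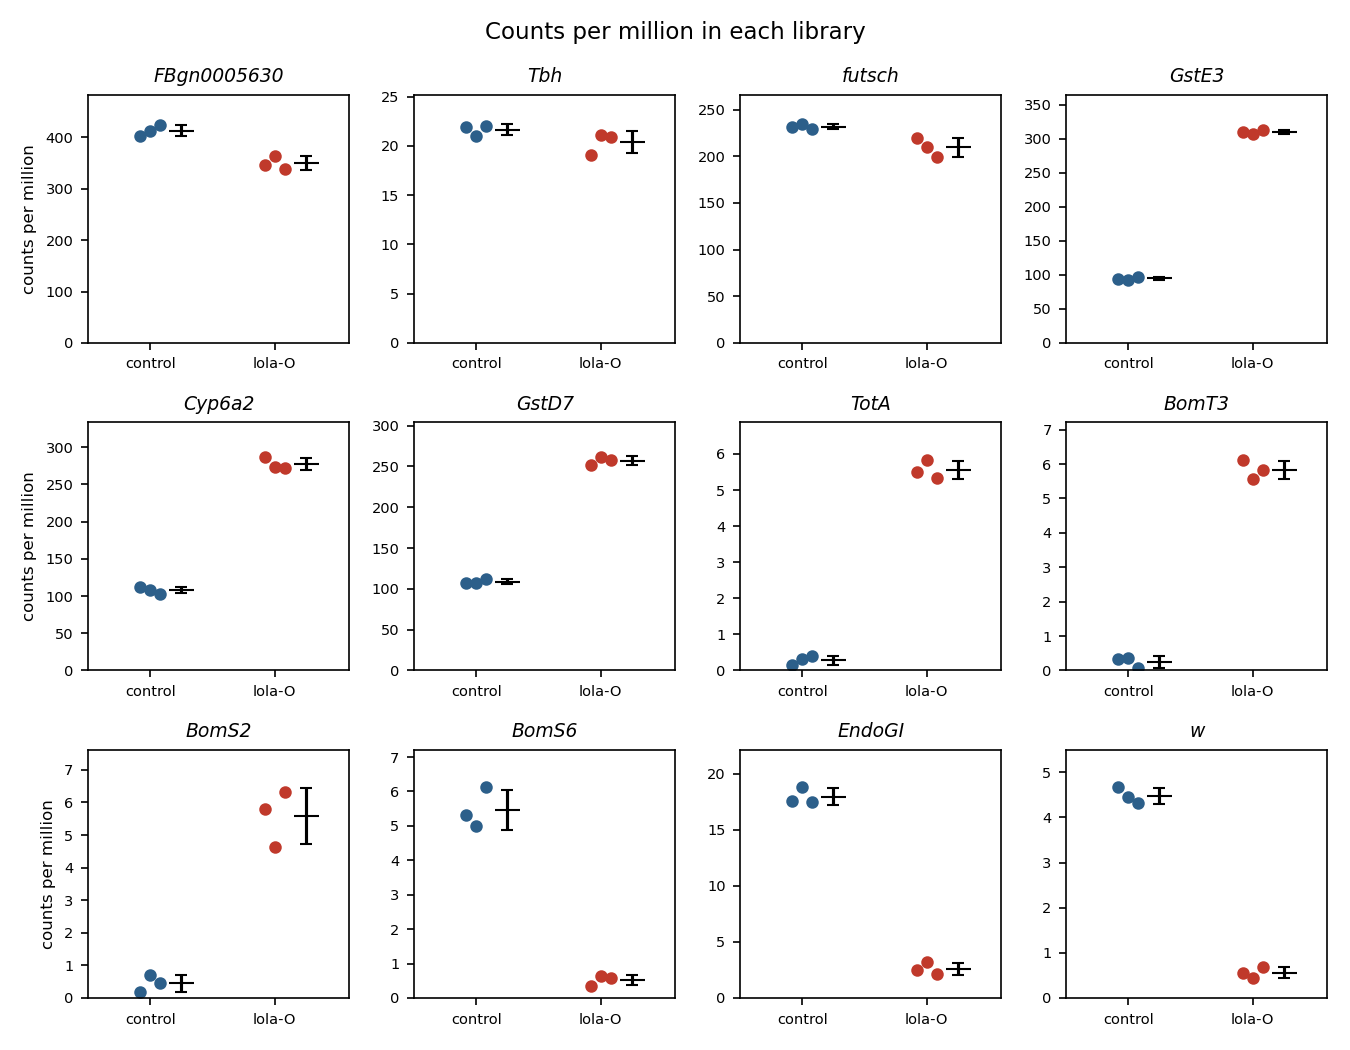
TMM-scaled CPM (vertical axes, from 0) of 12 genes in each of the 3 control libraries (blue points) and 3 lola-O mutant libraries (red points); black marks are the mean with an error bar of 1 SD. FBgn0005630 was 350 CPM in the mutants and 413 CPM in the controls, while GstE3 was 310 against 94.7 CPM and w was 0.563 against 4.48 CPM.

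Detoxification enzymes showed strong changes in both directions. Of 123 tested cytochrome P450, glutathione S-transferase and UDP-glycosyltransferase genes, 51 rose and 24 fell (52 and 24 adjusted over the list alone), 12 and 5 of them at least 2-fold. GstE3 (2R, 18400713 to 18401467) had 310 ± 3.11 CPM in the mutants and 94.7 ± 2.33 CPM in the controls (SD, n = 3 each), a log2 fold change of 1.71 (SE 0.033, edgeR adjusted p = 2.42e-51). Cyp6a2 rose by 1.37, GstD7 by 1.24 and Cyp6d5 by 1.10 on the log2 scale (edgeR adjusted p of 3.43e-43 or less). The list had a median log2 fold change of 0.086 and rose by camera (adjusted p = 0.00893; adjusted p = 0.374 with an estimated correlation). After the transcript-length correction the median was 0.042, with 46 genes higher and 28 lower, and the camera adjusted p was 0.0820. These are families of similar copies, so values of single members are uncertain.

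Cell cycle and replication genes shifted upward as a list, while most members did not pass alone. Of 21 tested, 8 rose, 1 fell and 12 did not pass (12 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.16. PCNA, the sliding clamp of DNA polymerase, rose from 24.0 ± 0.389 to 33.9 ± 0.679 CPM (SD, n = 3 each), a log2 fold change of 0.50 (SE 0.059, edgeR adjusted p = 8.94e-11). CycE rose by 0.38, Mcm5, a subunit of the replicative helicase, by 0.29 and RnrL, the large subunit of ribonucleotide reductase, by 0.28. The gene that fell was aurB, a mitotic kinase gene, at -0.83, named here after its value was seen. The list passed camera (adjusted p = 0.0422; adjusted p = 0.374 with an estimated correlation). Without mutant 2, mutant 3 or control 3 the camera adjusted p was 0.0995, 0.0605 and 0.0714.

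Ribosomal protein and respiratory chain genes rose together by small amounts. Of 84 tested ribosomal protein genes, 65 rose and 19 did not pass (72 rose adjusted over the list alone), with a median log2 fold change of 0.10. RpL23 rose from 1559 ± 53.9 to 1785 ± 53.7 CPM (SD, n = 3 each), a log2 fold change of 0.19 (SE 0.026, edgeR adjusted p = 4.71e-09). RpLP0-like rose by 0.31, RpL41 by 0.19 and RpS26 by 0.18; RpLP0-like is a ribosome assembly factor rather than a ribosomal protein. Of 61 tested nuclear genes of oxidative phosphorylation, 42 rose and 1 fell (47 and 1 adjusted over the list alone), with a median of 0.11; ND-ACP rose by 0.19, COX5A by 0.18, ATPsynO by 0.17 and Cyt-c1 by 0.16. Both lists passed camera (adjusted p = 9.04e-09 and 9.70e-07; adjusted p = 0.374 for each with an estimated correlation). After the transcript-length correction their medians were 0.026 and 0.030 and the camera adjusted p were 0.314 and 0.285. Then only 11 ribosomal protein genes were higher and 1 lower, and 10 and 3 genes of oxidative phosphorylation. Exons of RpLP0-like, RpL23, COX5A and ATPsynO overlap genes on the opposite strand, which leaves their counts uncertain.

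Axon guidance and adhesion genes were lower. Of 39 tested, 29 fell and 1 rose (30 and 1 adjusted over the list alone), with a median log2 fold change of -0.15. Dscam1, a cell-adhesion gene with many splice forms, had 179 ± 6.93 CPM in the mutants and 210 ± 6.55 CPM in the controls (SD, n = 3 each), a log2 fold change of -0.23 (SE 0.033, edgeR adjusted p = 1.31e-08). The midline repellent gene sli had -0.22, Mical, which acts downstream of plexin receptors, -0.21 and the teneurin gene Ten-m -0.19. futsch, which encodes a microtubule-associated protein of axons (X, 1409069 to 1453686), had 210 ± 9.90 CPM in the mutants and 232 ± 2.49 CPM in the controls (SD, n = 3 each), a log2 fold change of -0.14 (SE 0.032, edgeR adjusted p = 1.48e-04). The list passed camera (adjusted p = 2.94e-06; adjusted p = 0.374 with an estimated correlation). After the transcript-length correction the list median was -0.00056 with a camera adjusted p of 0.857, and 3 genes were higher and 3 lower. There futsch turned to a log2 fold change of 0.13 (edgeR adjusted p = 4.82e-04), and Dscam1, sli, Mical and Ten-m no longer passed edgeR (adjusted p of 0.0928 or more).

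Muscle structural genes were lower, and so were most neuron markers before the transcript-length correction. Of 16 tested muscle genes, 9 fell and 2 rose (10 and 2 adjusted over the list alone), with a median log2 fold change of -0.11. The projectin gene bt had 3451 ± 112 CPM in the mutants and 4771 ± 37.0 CPM in the controls (SD, n = 3 each), a log2 fold change of -0.47 (SE 0.024, edgeR adjusted p = 8.99e-27). The titin-like gene sls had -0.31, the Z-disc gene Zasp52 -0.23 and the myosin heavy chain gene Mhc -0.20. The muscle list passed camera (adjusted p = 0.0220; adjusted p = 0.374 with an estimated correlation), and its camera adjusted p was 0.0414 after the transcript-length correction, with a median of -0.062. Of 16 tested neuron markers, 9 fell and 1 rose, and the list did not pass camera (adjusted p = 0.0855, median -0.10); after the transcript-length correction 3 rose and 1 fell, with a median of 0.016. The calcium channel gene cac had -0.19, the syntaxin gene Syx1A -0.18 and the active-zone gene brp -0.16, whereas nAChRalpha6, an acetylcholine receptor subunit gene, rose by 0.71 (SE 0.040, edgeR adjusted p = 2.54e-21). With the transcript-length correction brp and sls turned to 0.040 and 0.065, and cac no longer passed edgeR (adjusted p = 0.917). The falls of bt, Zasp52 and Mhc shrank to -0.17, -0.092 and -0.063 and still passed edgeR.

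These small shifts ran along transcript length. Across 10110 tested genes with an annotated length, Spearman's rho between the log2 fold change and the longest transcript was -0.31; genes are not independent replicates, so no p is given. The decile with the shortest transcripts (66 to 777 bases) had a median log2 fold change of 0.097, with 285 genes higher and 103 lower. The decile with the longest transcripts (5347 to 71382 bases) had a median of -0.14, with 37 higher and 615 lower. The median transcript length was 882 bases for ribosomal protein genes, 802 for oxidative phosphorylation, 6206 for axon guidance and 6307 for neuron markers.

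**Figure D2:**
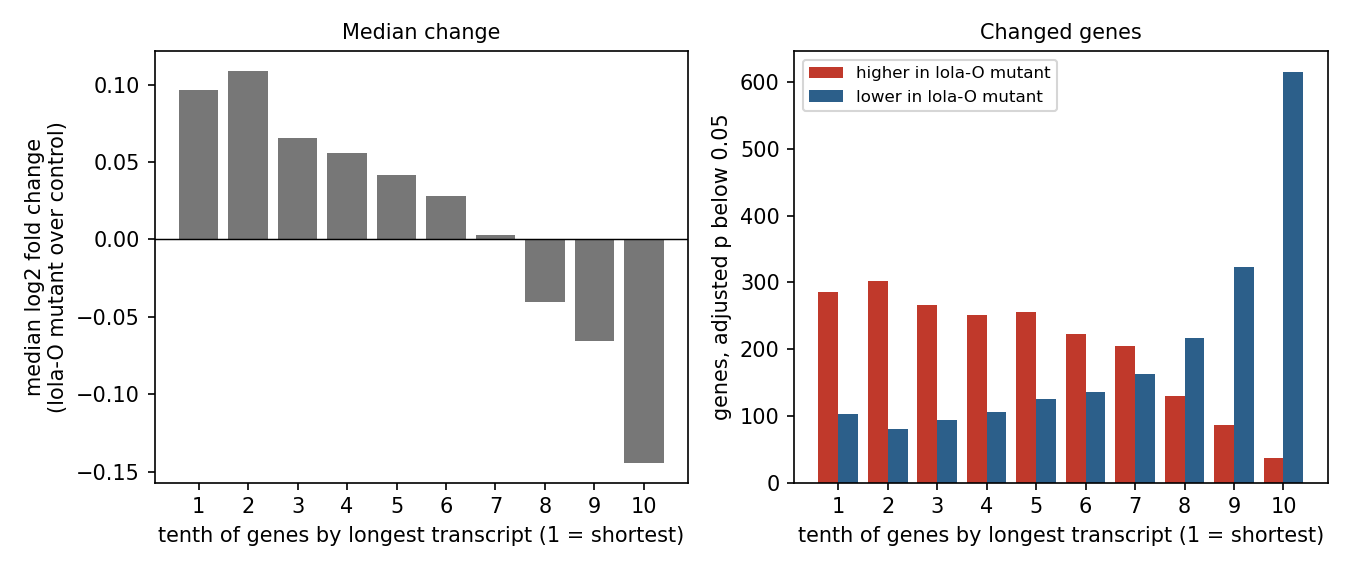
Tested genes in 10 groups of equal size by the length of their longest transcript (horizontal axes, 1 is the shortest). Left bars give the median log2 fold change, lola-O mutant over control, from 0.097 in the shortest group to -0.14 in the longest; right bars count genes with edgeR adjusted p below 0.05 that were higher (red) or lower (blue) in the mutant.

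Glia markers and cuticle protein genes moved in both directions, without a shift of the list before the transcript-length correction. Of 12 tested glia markers, 2 rose and 3 fell (camera adjusted p = 0.517, median -0.040). The blood-brain barrier receptor gene moody had -0.27 and the trehalose transporter gene Tret1-1 -0.19, while the astrocyte genes alrm and Eaat1 rose by 0.13 and 0.12; alrm did not pass DESeq2 (adjusted p = 0.0640). Of 65 tested cuticle protein genes, 12 rose and 11 fell (camera adjusted p = 0.443, median -0.051), 3 of them rising at least 2-fold. Cpr49Ad rose from 46.6 ± 0.782 to 85.1 ± 1.83 CPM (SD, n = 3 each), a log2 fold change of 0.87 (SE 0.043, edgeR adjusted p = 9.56e-28). Cpr67B went the other way at -0.70 and Cpr65Ay at -0.57. With the transcript-length correction the cuticle list passed camera in the direction of lower (adjusted p = 0.0281, median -0.14), and so did the chemosensory list (adjusted p = 0.0281, median -0.19). Of the cuticle genes, 8 were then higher and 18 lower.

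The octopamine and tyramine pathway changed in 2 of its 12 tested genes, both receptors. Octalpha2R had 61.7 ± 1.18 CPM in the mutants and 72.4 ± 1.39 CPM in the controls (SD, n = 3 each), a log2 fold change of -0.23 (SE 0.042, edgeR adjusted p = 4.70e-06), and Octbeta1R had -0.18 (edgeR adjusted p = 3.14e-04). Tbh, which encodes tyramine beta-hydroxylase, the enzyme that makes octopamine (X, 7995697 to 8027394), had 20.4 ± 1.11 CPM in the mutants and 21.6 ± 0.573 CPM in the controls (SD, n = 3 each), a log2 fold change of -0.088 (SE 0.068) that did not pass edgeR (adjusted p = 0.317). The tyrosine decarboxylase genes Tdc1 and Tdc2 had log2 fold changes of -0.057 (SE 0.047) and -0.092 (SE 0.12), and the vesicular transporter gene Vmat -0.037 (SE 0.029). The other receptors that did not pass were Oamb at -0.017, Octbeta2R at 0.078, Octbeta3R at -0.14, Oct-TyrR at 0.036, TyrR at -0.056 and TyrRII at -0.21. The list did not pass camera (adjusted p = 0.202). With the transcript-length correction neither Octalpha2R (adjusted p = 0.315) nor Octbeta1R (0.0870) passed edgeR, while Octbeta2R at 0.20 and Vmat at 0.10 did (5.94e-04 and 0.00270).

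Immune genes moved in both directions. Of 29 tested antimicrobial peptide and immune signalling genes, 13 rose and 12 fell, 8 rising and 2 falling at least 2-fold; the list as a whole did not pass camera (adjusted p = 0.658, median 0.020, mean 0.87). All 29 are named, a choice made after their values were seen. Beside the Bom and Tot genes above, the members that rose were BomS1 by 2.66, BomS3 by 1.596, PGRP-SB1 by 0.99, BomS5 by 0.80, Drsl2 by 0.36, PGRP-SC1b by 0.22 and PGRP-LB by 0.12. Beside BomS6, those that fell were PGRP-SC2, which encodes a secreted amidase that degrades peptidoglycan, at -1.21, PGRP-SC1a at -0.65, PGRP-LF at -0.42, Dif at -0.38, dl at -0.30, spz at -0.25, cact at -0.20, IM33 at -0.20, Tl at -0.17, PGRP-LC at -0.15 and Rel at -0.15. PGRP-SD at 0.49, PGRP-LE at 0.020, nec at 0.0033 and PGRP-SA at -0.47 did not pass edgeR. The 13 attacin, cecropin, diptericin, defensin, drosocin and metchnikowin genes fell below the expression filter, with 56 counts summed over the 3 mutants and 48 over the 3 controls.

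**Figure D3:**
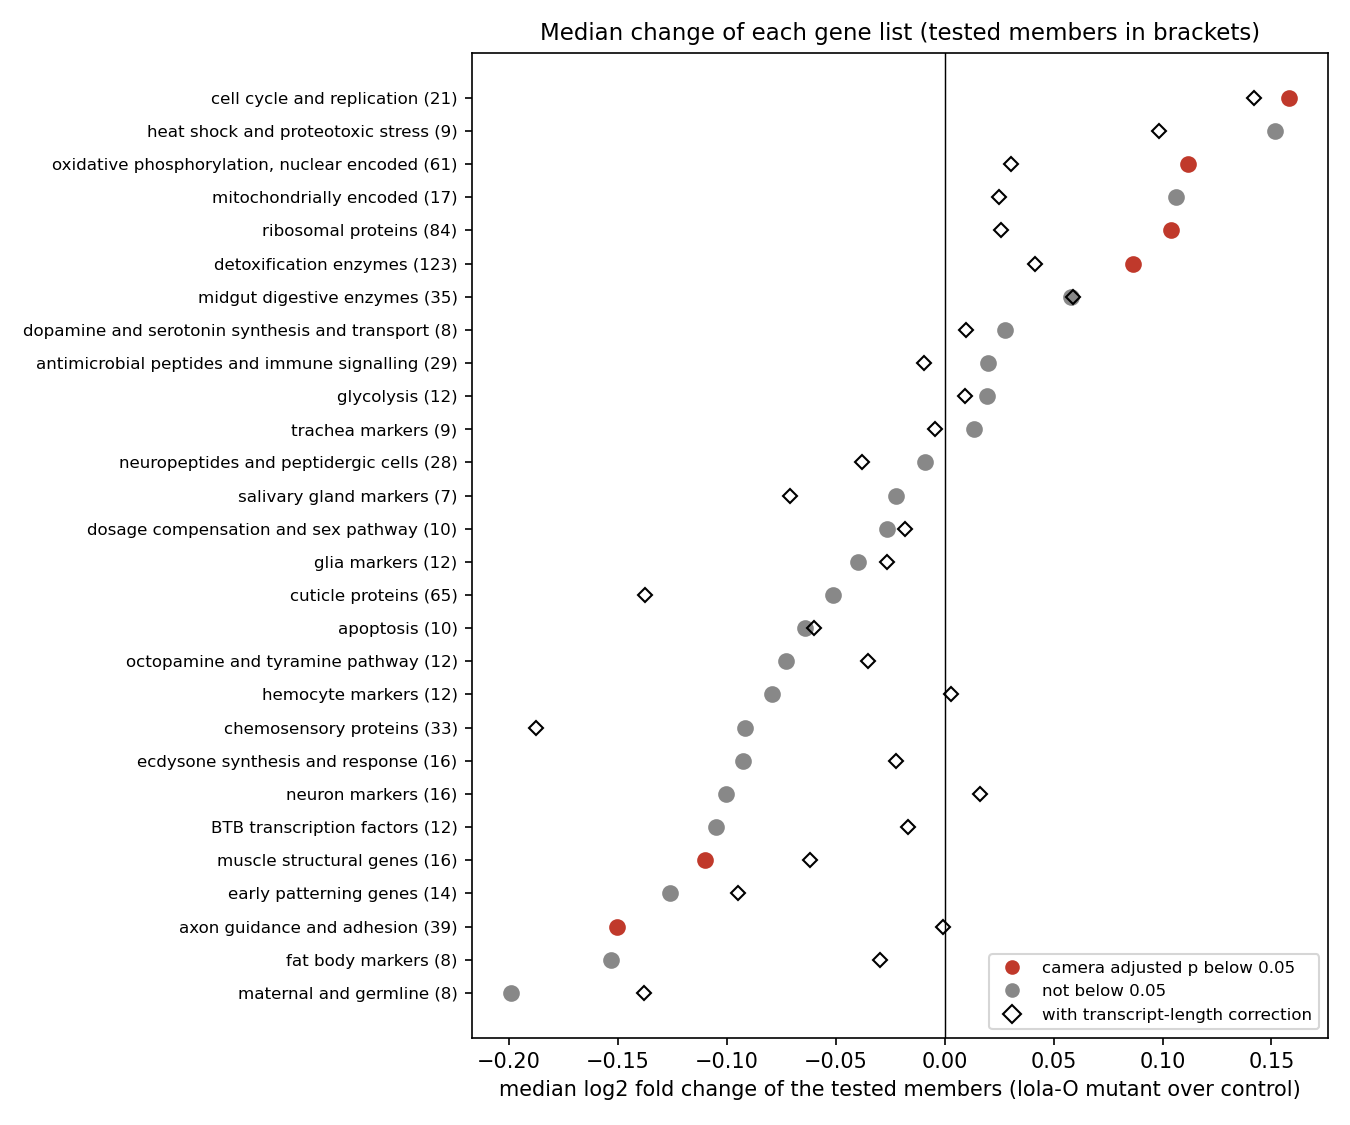
Median log2 fold change, lola-O mutant over control (horizontal axis), of the tested members of each of 28 gene lists (vertical axis, tested members in brackets). Red points passed camera at adjusted p below 0.05 and grey points did not; open diamonds are medians after the transcript-length correction, at which the axon guidance median moved from -0.15 to -0.00056.

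The remaining lists did not pass camera. Midgut digestive enzyme genes changed often and in both directions, 15 higher and 13 lower of 35 tested (16 and 13 adjusted over the list alone; adjusted p = 0.3002). Of the hemocyte markers 1 rose and 5 fell of 12 (camera adjusted p = 0.202), and of the fat body markers 2 rose and 5 fell of 8 (adjusted p = 0.281), with a median of -0.15, a mean of 0.14 and a downward camera direction. Trachea markers had 4 lower of 9 (adjusted p = 0.282), with a median of 0.013, a mean of -0.070 and a downward direction. Apoptosis genes had 2 lower of 10 (adjusted p = 0.658), with a median of -0.064, a mean of 0.027 and a downward direction. Salivary gland markers had 1 lower of 7 (camera adjusted p = 0.733), BTB transcription factors 6 lower of 12 (0.0855), maternal and germline genes 4 lower of 8 (0.202), and dosage compensation and sex pathway genes 2 lower of 10 (0.530). Early patterning genes had 2 lower of 14 (camera adjusted p = 0.205), of which the count adjusted over the list alone kept 0. Ecdysone genes had 2 higher and 4 lower of 16 (camera adjusted p = 0.202), glycolysis genes 3 and 2 of 12 (0.658; 5 and 2 adjusted over the list alone), and chemosensory genes 1 and 6 of 33 (0.202; 1 and 3 adjusted over the list alone). Heat shock genes had 3 higher of 9 (camera adjusted p = 0.129, median 0.15) and dopamine and serotonin genes 1 higher of 8 (0.443). Neuropeptide genes had 2 higher of 28 (0.788; 1 adjusted over the list alone), with a median of -0.0091, a mean of 0.028 and an upward direction. The 17 tested mitochondrially encoded genes had a median of 0.11 (camera adjusted p = 0.164); edgeR, DESeq2 and limma-voom passed 0, 1 and 9 of them, with 3 at an unadjusted edgeR p below 0.05. For the neuron, glia, cuticle, octopamine, immune and other lists with no second pair of counts, the counts adjusted over the list alone were the same.

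Strong changes gathered on the second chromosome, which carries lola and differs between the genotypes. Of 1781 tested genes on 2L, 47 (2.64%) changed at least 2-fold, and of 2051 on 2R, 55 (2.68%); the odds ratios against all other arms were 1.86 (95% interval 1.296 to 2.65) and 1.97 (1.39 to 2.75), with Fisher's exact adjusted p of 0.00127 and 2.68e-04. The X had 9 of 1625 (odds ratio 0.295, adjusted p = 2.45e-04) and 3L 19 of 2011 (0.515, adjusted p = 0.00658), while 3R had 36 of 2531 (0.824, adjusted p = 0.407). With all changed genes counted, the odds ratios were 1.201 for 2L and 1.21 for 2R, 0.853 for X, 0.893 for 3L, 0.873 for 3R and 2.06 for chromosome 4, each with a Fisher's exact adjusted p of 0.0285 or less. On chromosome 4, 51 of 89 genes changed, but 0 of 89 by at least 2-fold in edgeR (0 at an unadjusted p below 0.05; 0 with DESeq2 and limma-voom, 1 and 0 unadjusted), and the odds ratio of all changed genes was 1.10 (adjusted p = 0.731) after the transcript-length correction. For 3L, the odds ratio without mutant 3 was 0.909 (adjusted p = 0.0777). Fisher's exact test takes genes as independent, but some of the 2-fold genes are neighbours, such as BomBc1, BomS1, BomS2 and BomS3 on 2R. The intervals may therefore be too narrow and the Fisher's exact p too small, here and in the tests near lola.

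Genes near lola were examined as well. Within 1 Mb of its midpoint, 100 of 212 tested genes changed (47.2%, against 39.5% elsewhere), an odds ratio of 1.37 (95% interval 1.03 to 1.81, 2-sided Fisher's exact p = 0.0276). Against the rest of the second chromosome alone the odds ratio was 1.18 (Fisher's exact p = 0.254), and within 0.5 Mb it was 1.203 (Fisher's exact p = 0.395); within 2 Mb it was 1.302 (Fisher's exact p = 0.00718). Changes of at least 2-fold were seen in 7 of the 212 genes, an odds ratio of 2.09 (0.815 to 4.48, Fisher's exact p = 0.0894), and within 2 Mb in 13 of 441, an odds ratio of 1.88 (0.973 to 3.35, Fisher's exact p = 0.0349). Against the rest of the second chromosome alone, these 2 odds ratios were 1.27 and 1.13 (Fisher's exact p = 0.508 and 0.638).

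**Figure D4:**
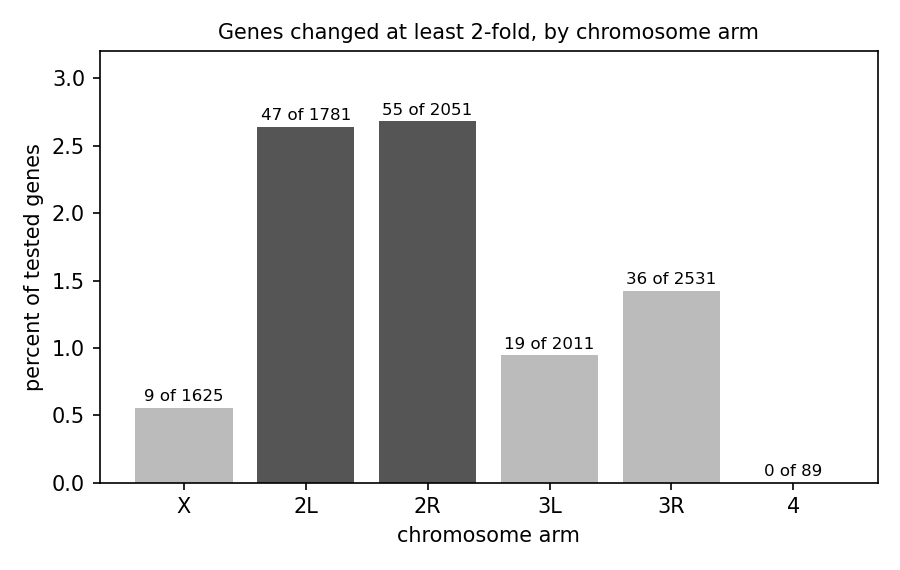
Percent of tested genes (vertical axis, from 0) on each chromosome arm (horizontal axis) that changed at least 2-fold with edgeR adjusted p below 0.05; labels give the counts, and dark bars mark the second chromosome. 2L and 2R stand at 2.64% and 2.68%, above X at 0.554%, 3L at 0.945% and 3R at 1.42%.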

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

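The transcript-length correction, the comparison within the second chromosome and leaving out samples for the position tests were chosen after the data were seen; all other settings here were planned. The count of 4093 changed genes stayed within 1.5 times under every setting: 3003 with DESeq2 (2977 shared), 4043 with limma-voom (3998 shared), 4064 without a filter, 3481 to 3872 with a sample left out and 3288 with the transcript-length correction (2817 shared). No scaling moved the median of all genes by over 0.01. The 167 changes of at least 2-fold became 72 under the filter of 5 CPM, because fewer low genes were tested, 247 without a filter and 184 to 198 with a sample left out. FBgn0005630 ranged from -0.27 to -0.21 and Tbh from -0.11 to -0.042 with a sample left out. The length correction was not applied to FBgn0005630, which did not match the annotation. For the other 70 named genes, 1015 of 1034 alternative values kept both their sign and their call. Of the rest, 7 kept the sign but no longer passed, 1 kept the sign and newly passed, and 11 reversed. The length correction turned futsch (0.13) and, of these genes, Vmat (0.10), Oamb (0.043), TyrR (0.039), Mical (0.025), Ten-m (0.0082), sls (0.065) and brp (0.040), whose transcripts are long. Oamb also ranged from -0.053 to 0.017 and TyrR from -0.095 to 0.014 with a sample left out; neither passed.

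Of 6 lists, 0 passed camera with an estimated correlation (adjusted p = 0.374 for each of the 6; 1 list at an unadjusted p below 0.05), and 19 of 28 lists passed fry, which asks whether the genes of a list move and not whether they move more than others. With the length correction 4 lists passed, 2 of them among the 6; axon guidance had 0.857, ribosomal proteins 0.314, oxidative phosphorylation 0.285 and detoxification 0.0820. With a sample left out, the cell cycle list ranged from 0.0222 to 0.0995. Chromosome 3R at 2-fold had an odds ratio of 0.824 and chromosome 4 of 0, where few genes reach 2-fold; chromosome 4 had 1.10 with the length correction. 3L ranged from 0.842 to 0.909 with a sample left out. Near lola the call ended within 0.5 Mb (odds ratio 1.203), at 2-fold (2.09) and within the second chromosome (1.18). It held within 2 Mb (1.302), with the length correction (1.61), with a replicate block (1.38) and with each sample left out (1.39 to 1.52). Where no cause is named, the cause was not tested. Replicate numbers did not pair the samples: deviations of samples with the same number correlated at 0.023, -0.028 and 0.043, and not every sample correlated best with its own number. A replicate block gave 4077 changed genes (4018 shared) and 6 lists and changed no call of a list, an arm or a named gene. In simulated counts, 1.2-fold changes were recovered for 64% of genes.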

Other observations

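The genes in this paragraph were chosen after their values were seen. Beyond the 4 named detoxification genes, Cyp6a14 rose by 1.95 on the log2 scale, Ugt37A2 by 1.70 and Cyp28d2 by 1.37, and Mdr50, which encodes an ABC transporter of the multidrug resistance type, by 1.09. The juvenile hormone epoxide hydrolase genes Jheh2 and Jheh1 rose by 0.85 (SE 0.028) and 0.75 (SE 0.030). Cyp6w1, Cyp6a20 and Cyp9b1 went the other way, at -1.41, -1.48 and -1.56. ple, which encodes the tyrosine hydroxylase of dopamine synthesis and cuticle tanning, rose by 0.60 (SE 0.052), while Ddc had 0.16 (SE 0.072) and did not pass edgeR (adjusted p = 0.0764). Of digestive enzyme genes, Jon44E rose by 0.91 and Mal-A1 by 0.82, while mag had -1.41 and alphaTry -0.73. Top3alpha, a DNA topoisomerase gene, had -1.63 (SE 0.076). On 3R, 4 genes that start between 17610856 and 17630717 rose together: Edg91, which encodes a cuticle protein, by 2.36, CG34281 by 1.74, CG14327 by 3.07 and CG43175 by 3.17. On 2L, lncRNA:CR44701, at -5.29, starts at 9887039, upstream of nAChRalpha6 (minus strand, 9793317 to 9886250), which rose by 0.71. Of immune and hemocyte genes outside the fixed immune list, SPH93, Listericin and Dso2 rose by 2.71, 2.14 and 1.44, while Tep2 had -0.19, Tep4 -0.26, Hml -0.27 and NimC1 -0.69.

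The comparison of list medians with matched lists and the splits of the samples were set before their results were seen, and all other tests below were chosen after. There are 10 ways to split 6 samples into 3 and 3, too few for a share under 0.05. The real split, the 1 of 10 with the highest count each time, gave 4093 changed genes, 2087 higher, 2006 lower and 167 at least 2-fold, against at most 0 in the other splits by edgeR, DESeq2 and limma-voom (at most 189 at an unadjusted edgeR p below 0.05). It gave 6 lists by camera at the preset correlation, against 0 to 5 in the other splits, where no gene passed. The number of lists passing camera therefore hardly set the real split apart. Each other split puts both genotypes on both sides, so the genotype difference widens the spread within its sides. The 0 changed genes there therefore do not measure how many calls would arise without a genotype difference.

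The first pattern is the run of small shifts along transcript length, seen with opposite sign in the 3 mutants and the 3 controls; against random lists matched on length and level, the axon guidance median stood at percentile 13.66, ribosomal proteins at 36.46 and oxidative phosphorylation at 52.72, so their shifts are consistent with the length trend alone. Cell cycle genes (percentile 99.94) and muscle genes (0.98) moved beyond matched lists; so did detoxification genes (97.81), narrowly, and their camera call ended with the correction as the median went from 0.086 to 0.042. Of lists that did not pass camera, cuticle (0), chemosensory (0.9), midgut (1.19) and fat body (2.12) genes also lay below matched lists. A change of neural genes alone as the whole cause was checked on the 16 muscle genes. Their slope of log2 CPM on log2 length was lower in the mutants (difference -0.070, 95% Welch interval -0.093 to -0.047, 3 libraries each). A fall with length was thus also seen in genes that are not neural. The interval holds these 16 genes fixed, and the long genes bt and sls both fell. Because muscle genes moved beyond matched lists, the slope may be a change of their own, so it does not decide the cause of the wider trend. A difference in RNA or library preparation between the 2 sets of libraries cannot be told apart from a change in the embryos, because either would separate the groups and the labels give no batch. All 6 libraries went the way of their group, which both would give. Deviations were taken from the mean of all 6 libraries, so the opposite signs of the groups largely restate the trend.

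The second pattern is the gathering of 2-fold changes on the second chromosome, 102 of 3832 genes against 64 of 6256 elsewhere, an odds ratio of 2.65 (95% interval 1.91 to 3.69), which was 1.93 to 2.76 with a sample left out. Neighbouring genes are not independent, so the intervals in this paragraph may be too narrow. A local effect around lola as the whole cause is argued against by 2L, which does not carry lola: 47 of its 1781 genes changed 2-fold, an odds ratio of 2.62 (1.75 to 3.90) against the genes off the second chromosome. Sequence differences between the 2 second chromosomes, unrelated to lola-O, are a candidate explanation; without genes within 2 Mb of lola and without the fixed lists the odds ratio was 2.74 (1.89 to 4.01). They cannot be told apart from an effect of lola-O on genes that lie there, because mutation and chromosome differ together between the groups, and this effect was not tested.

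The third pattern is the rise of Bom and Tot genes with a fall of BomS6. A general antimicrobial response stays open: 13 other antimicrobial peptide genes had a ratio of summed counts of 1.297 (0.866 to 1.95, counting error only), but 0 of them passed the expression filter, so they decide nothing. Drs, an antimicrobial peptide gene that is also on the fixed list, was not part of this sum. Other immune genes went both ways, and genes outside the fixed list were not tested as a set. Variants beside the genes on the second chromosome cannot by themselves account for the 4 raised genes on 3R. These lie in neighbouring pairs, TotA with TotC and BomT3 with BomBc3. Sequence differences beside them on 3R, or on other chromosomes, were not tested and stay open. For the 4 raised genes on 2R, variants cannot be told apart from regulation, since no sequence was examined. An effect of lola-O on these genes was not tested and stays open.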
